A study of Drosophila melanogaster with 19 samples.

How the data were processed

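Armi iCLIP, Armi CLIPPARE and Piwi small RNA libraries of OSC were used as the deposited tables of RPM. Per the labels, cells for iCLIP and CLIPPARE were crosslinked with UV, RNA was digested with RNase T1 and bound RNA was recovered with anti-Armi or, for Myc-Armi, anti-Myc antibody. Both knockdown Piwi libraries list an anti-Myc antibody in their labels, while their protocol describes an anti-Piwi antibody, and the genotype label of the Yb KD Piwi library names EGFP RNAi. Per the submitters' processing notes, adapters were trimmed with cutadapt and reads aligned with STAR to dm6; versions, the counting step, the treatment of reads with several hits or on the antisense strand, and the removal of duplicates by the random bases are not stated there. Signal shared by near-identical or overlapping genes therefore cannot be assigned with certainty.

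The deposited values are RPM, 1 per FlyBase transcript. Every value was a whole multiple of 1 step per column (tolerance 0.1 of a read), so whole reads were recovered, and the implied total of reads was taken from the step. The tables held 12.8 to 63.8% of that total, and which reads make up the total is not stated. The untreated and CLIPPARE tables hold 13929 transcripts, and the others 12013 with a symbol, after 107 repeated lines were dropped. The 1916 transcripts without a symbol carried 9.58 to 11.6% of the RPM in the tables that have them. Of the symbols, 10221 were current and 1782 were synonyms in the reference table (Release 6 plus ISO1 MT), and 10 were not in it. The loci in the tables use chromosome names absent from that reference for 97 transcripts, such as 2RHet and Uextra, and no locus end on 2R, 3R or X equals that of the reference, so they follow another assembly than dm6 and no positions are given.

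Groups were taken from the sample titles. The deposited RPM of the knockdown iCLIP and Myc-Armi iCLIP have 1 column per condition although the labels list 2 libraries; how these were joined is not stated. The test planned for these, limma on replicates, could not be run, so they were described as the Piwi libraries were: values, ratios with exact conditional binomial intervals at 95%, and list medians with their percentile among 10000 random lists of the same size matched on mean RPM. For Zuc KD CLIPPARE, log2(RPM + 1) of transcripts with a mean of at least 5 RPM was fitted with limma 3.58.1 (lmFit and eBayes with trend) in R 4.3.3 and called at a Benjamini-Hochberg adjusted p of 0.05, two-sided. Lists were tested with camera and, as an alternative, fry. Log2 ratios used a pseudocount of 1 RPM. List medians used transcripts with a mean of at least 5 RPM, except for Piwi small RNA, where every transcript with a value was used. Where most transcripts shifted together, values were also given relative to the median of transcripts with a mean of at least 5 RPM. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the rest.

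Comparisons, tests, alternatives, gene lists and the rule for named genes were fixed before the data were examined. Named were, for CLIPPARE, the 8 largest changes each way among transcripts past the threshold whose groups did not overlap and with a mean of at least 20 RPM; for comparisons without replicates, the 8 largest and 8 smallest ratios at a mean of at least 100 RPM, a rule written for the Piwi libraries and used for the other columns as well; for untreated cells, the 10 highest in each assay; and in each comparison armi, piwi, fs(1)Yb, zuc, tj, members of highest RPM of each list, and transcripts of opposite direction. The lists were cytosolic ribosomal protein, translation factor, heat shock and chaperone, cytoskeleton, nonsense-mediated decay and helicase, piRNA pathway, follicle and somatic gonad, germline marker and hemocyte marker genes, the 50 highest Piwi (Piwi-rich) and the 50 highest Armi (Armi-rich) transcripts, and the 4 classes of the tables. Lists of piRNA clusters, mitochondrial, small nuclear, transfer and ribosomal RNAs matched 0 transcripts by symbol, and of 34 histone transcripts matched none reached a mean of 5 RPM. The transposon lists were not matched by name, because no transcript was marked as a transposon and some names are also those of genes.

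Alternatives were pseudocounts of 0.1 and 5 RPM, no filter and a filter of 20 RPM, centring, no trend, a replicate block, edgeR 4.0.16 (quasi-likelihood with TMM) and DESeq2 1.42.0 on recovered reads, and leaving out each replicate. The methods were tested on simulated data. For Zuc KD, limma recovered 69.1% of 2-fold and 100% of 4-fold changes among 3916 transcripts with 8 false calls. The simulated libraries were drawn around 1 mean per transcript. They left out the shift between the control KD libraries, whose median log2 was 0.48, and 0.81 in the High class. Recovery and false calls in the real data may therefore be worse. For the comparison of the Yb KD columns, a simulated High class lowered 2-fold gave a High minus Low difference of −1.00, and an unchanged one 0.0092. Transposon and piRNA cluster reads, raw reads and RNA abundance were not analysed here.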

Results

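Ovarian somatic cells (OSC) are a Drosophila line from ovarian follicle cells in which the protein Piwi carries PIWI-interacting RNAs (piRNAs), the small RNAs that silence transposons. Armitage (Armi) is an RNA helicase that binds the long precursors of these piRNAs. Yb, the product of fs(1)Yb, and Zucchini (Zuc), an endonuclease, are further factors of the same pathway. RNA crosslinked to Armi was read by iCLIP in untreated cells (2 libraries), after a control knockdown (KD) against EGFP and a Yb KD (2 libraries each per the labels), and for Myc-tagged Armi, wild type (WT) or with the substitution D862A or R949A (2 libraries each per the labels). The 5′ ends of Armi-bound RNA were read by CLIPPARE, in which an adapter is ligated to the 5′ end before RNase digestion, after control KD and Zuc KD (2 libraries each). Piwi-bound small RNA was read in untreated, control KD and Yb KD cells (1 library each).

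All values are RPM, reads per M of reads, per FlyBase transcript. No piRNA cluster such as flam and no structural RNA looked for was found by symbol. Names of transposons were not matched, since some are also gene names and no transcript was marked as a transposon. The 1916 transcripts of the untreated and CLIPPARE tables without a symbol were not searched. The tables of the Yb KD iCLIP and of the Myc-Armi iCLIP give 1 column per condition, so these values, like those of Piwi, have no replicates and no test between conditions. The reads implied per column, in M (mega), were 6.97 and 8.92 M for untreated Armi, 10.4 M for control KD and 4.45 M for Yb KD iCLIP, 2.54 M for WT, 6.27 M for D862A and 5.70 M for R949A. In CLIPPARE they were 7.82 and 5.38 M for control KD and 5.83 and 5.71 M for Zuc KD, and for Piwi small RNA 1.79 M untreated, 0.813 M in control KD and 0.853 M in the library labelled Yb KD. Intervals given for ratios are 95% and cover counting error only, since reads come from PCR and the use of the random bases to remove duplicates is not stated. The authors' tables sort transcripts with a symbol by piRNA level into High (238), Middle (742), Low (5488) and Zero (5545), and these classes follow the RPM in the untreated Piwi library, from 100 RPM up for High, from 20 RPM for Middle and at 0 RPM for Zero.

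The first comparison set the RNAs bound by Armi beside those that gave Piwi-bound small RNAs in untreated cells. The mRNA of traffic jam (tj), a follicle-cell transcription factor gene long known as a source of genic piRNAs, was the most abundant transcript in both assays, at 2897 ± 203 RPM in Armi iCLIP (SD, n = 2) and 2958 RPM in Piwi small RNA. The mRNAs of brat, a translational repressor, and dm, the fly Myc, were also among the 10 highest in both assays, as was the transcript FBtr0309865, which the files leave without a symbol. Cytosolic ribosomal protein mRNAs together had 4204 RPM in Armi iCLIP and 1186 RPM in Piwi small RNA, which is 3.54-fold lower. RpL41 differed far more, with 529 ± 54.5 RPM in Armi iCLIP and 4.47 RPM in Piwi small RNA.

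The 10 transcripts of highest Armi signal were tj, FBtr0309865, brat, dm, CG11360, CG10289, l(2)gl, Sec16, Eip63E and path. The 10 of highest Piwi signal were tj, CG32000, dm, FBtr0309865, CG17912, Nipped-A, CG32791, brat, Baldspot and lama. Of the 50 highest transcripts of each assay, 30 were shared. High-class transcripts made up 41.7% and 41.8% of the reads in the table in the Armi replicates and 54.4% in the Piwi library (exact binomial interval 54.2 to 54.6%). The class follows the RPM of this same Piwi library, so its larger share there is in part fixed by that choice. The median log2 ratio of Piwi to Armi was −0.66 over 3189 transcripts. Relative to it, cytosolic ribosomal protein genes lay at −0.92 (66 of 76 below) and translation factors at −1.08 (10 of 11 below), with medians at the 0 and 0.31 percentiles of 10000 random lists matched on mean RPM. Pathway genes bound by Armi included armi itself (140 ± 10.4 RPM in Armi iCLIP, 135 RPM in Piwi small RNA), piwi (198 ± 20.1 and 92.7 RPM) and fs(1)Yb (222 ± 10.4 and 83.2 RPM). Spearman's rho between the assays was 0.70 across 3708 transcripts, which are not independent replicates. The Armi replicates correlated at r = 0.988, with a spread 2.12 times that of counting error in chi-square per degree of freedom.

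**Figure D1:**
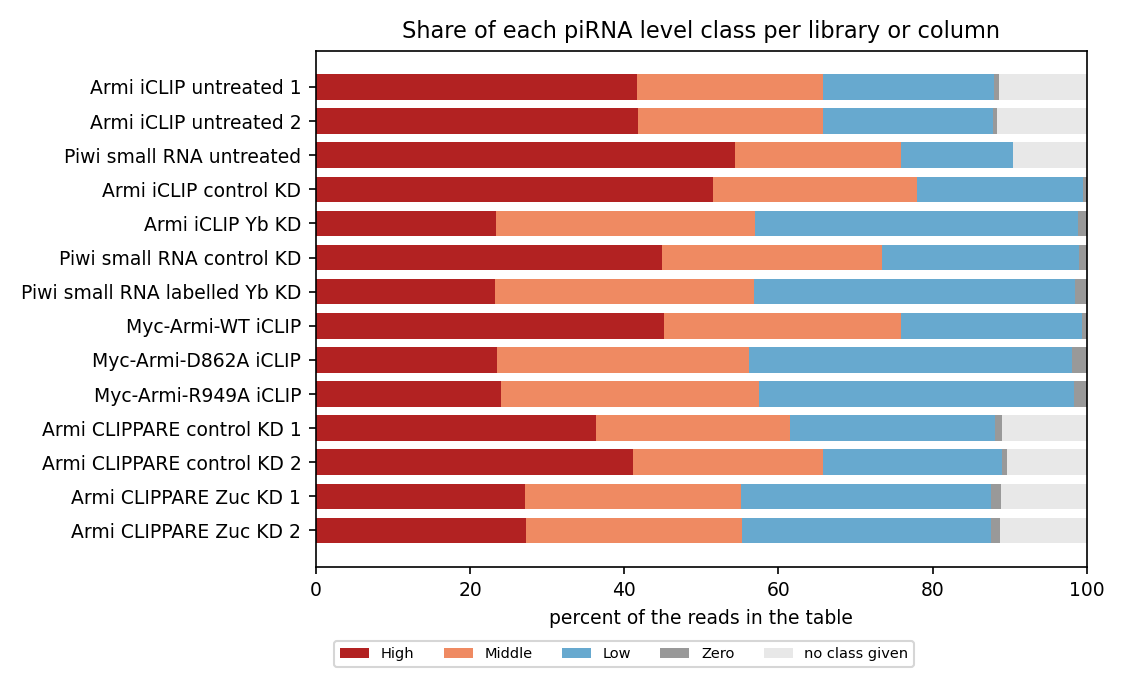
Bars give the percent of the reads in each table that fell on transcripts of each piRNA level class, per library or, for Yb KD iCLIP and Myc-Armi iCLIP, per column; transcripts without a symbol have no class and are absent from the tables of the knockdown iCLIP, Myc-Armi iCLIP and knockdown Piwi data. The High class held 51.6% in control KD and 23.4% in Yb KD Armi iCLIP, and 45.2%, 23.5% and 24.0% for WT, D862A and R949A.

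The Yb KD asks which RNAs Armi binds when Yb is missing. The fs(1)Yb mRNA itself was 11.3-fold lower in the Yb KD column (9.30 to 13.8; 269 to 23.8 RPM), but this is Armi signal and not the level of the mRNA, so it does not by itself check the knockdown. The signal of the tj mRNA was lower, from 4510 to 1170 RPM (3.85-fold lower, 3.74 to 3.97), as was that of the brat mRNA, from 3109 to 520 RPM. Of 4039 transcripts with a mean of at least 5 RPM, 3557 had more RPM in the Yb KD column, and the median was 2.99-fold higher. The mRNA of the Hippo-pathway gene ex lay far above this median, going from 2.30 to 260 RPM (113-fold higher, 75.4 to 177). All 80 ribosomal protein mRNAs measured, and the mRNAs of actin and tubulin, had more RPM in the Yb KD column.

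The mRNA of Invadolysin, a metalloprotease, had the smallest ratio at 397 to 24.3 RPM (16.3-fold lower, 13.49 to 19.96). After it and fs(1)Yb came CG13865 (316 to 28.3 RPM), Sec16, a protein of ER exit sites (1401 to 151 RPM), CG11360 (1900 to 226 RPM), Pis (194 to 22.9 RPM), CG31875 (182.5 to 23.2 RPM) and RhoGAP92B (574 to 79.2 RPM). After ex, the largest ratios were those of CG4168 (9.21 to 192 RPM), Spn (10.7 to 211 RPM), the stress-response factor Xrp1 (66.8 to 756 RPM), CG11873 (58.6 to 608 RPM), zormin (22.7 to 210 RPM), RpS7 (20.4 to 189 RPM) and betaTub56D (32.6 to 291 RPM). Xrp1 belongs to the High class, so membership of that class did not fix the direction.

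The table held 20.505% of all reads in control KD and 34.2% in Yb KD, and the median log2 ratio over 4039 transcripts was 1.58. The High class had a median of −0.54, which is 2.12 below that of the table, with 217 of 238 transcripts below it. No random list of matched RPM gave a median as low. The Middle, Low and Zero classes had medians of 0.99, 1.72 and 1.84, and the Middle class also lay below the table median, by 0.59. All 48 Piwi-rich genes, the transcripts of highest untreated Piwi signal with a symbol, lay below the table median (median −1.54), as did 43 of 46 Armi-rich genes (median −1.65). Relative to the table median, ribosomal protein genes were at 0.87 (74 of 80 above), cytoskeleton genes such as Act5C (314 to 1552 RPM) at 0.75, heat shock and chaperone genes such as Hsc70-4 (153 to 757 RPM) at 0.71 and translation factors such as pAbp (599 to 2424 RPM) at 0.48. Their medians were at the 100, 99.96, 99.57 and 98.03 percentiles of matched random lists. Follicle and somatic gonad genes, hemocyte markers and nonsense-mediated decay genes lay at 0.26, 0.63 and 0.36, at the 93.06, 92.34 and 93.14 percentiles. Germline markers such as spn-E (287 to 303 RPM) had a median of 0.65, higher as given but 0.93 below the table median, at the 3.91 percentile. The armi mRNA was 2.89-fold higher, the piwi mRNA 1.43-fold higher and the zuc mRNA 2.68-fold higher as given, but all 3 lay below the table median, by 0.057, 1.07 and 0.38.

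**Figure D2:**
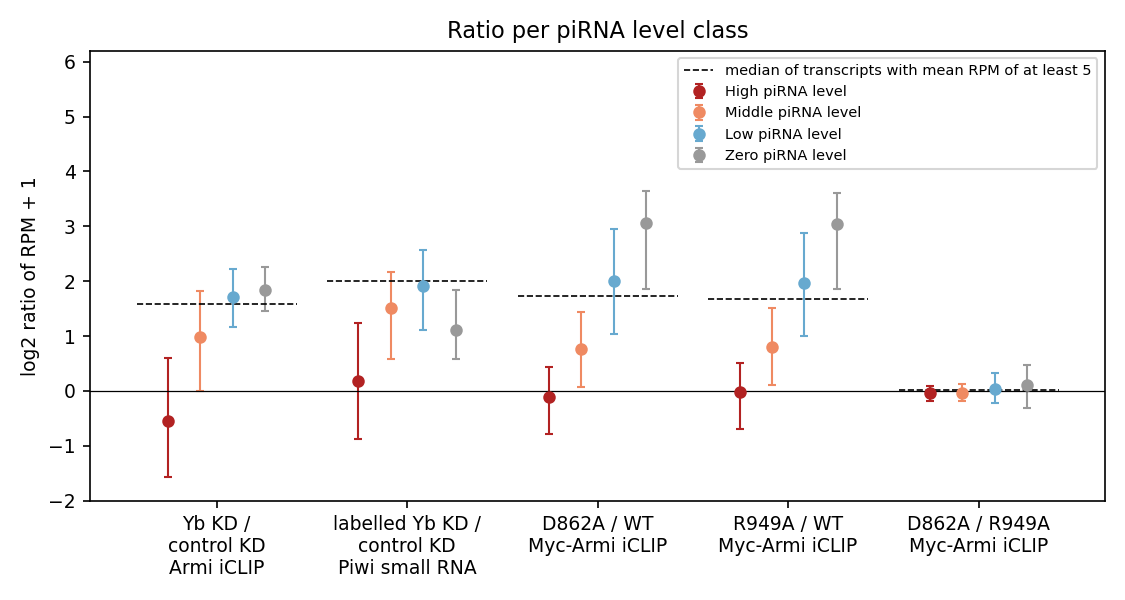
Points give the median log2 ratio of RPM + 1 per piRNA level class for the comparisons without replicates, over every transcript with a value in Piwi small RNA, bars the interquartile range, and dashed lines the median of transcripts with a mean of at least 5 RPM. The High class lay below the dashed line by 2.12 in Yb KD Armi iCLIP, 1.82 in Piwi small RNA, 1.83 for D862A and 1.69 for R949A.

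The Piwi libraries ask what Piwi carries when Yb is missing. In the library labelled Yb KD, Piwi-bound reads of tj were 1.79-fold lower (1.70 to 1.89; 4303 to 2402 RPM), those of brat went from 3396 to 1202 RPM, and those of CG11360 from 1514 to 236 RPM. Low-class transcripts had a median of 3.75-fold higher as given. Among them ex and CHKov1 lay far above this median. Reads of ex went from 16.0 to 785 RPM (49.1-fold higher, 28.5 to 92.7). Those of CHKov1 went from 3.69 RPM, or 3 reads, to 244 RPM (66.0-fold higher, 22.3 to 323). Reads of the piwi mRNA went from 650 to 3364 RPM (5.18-fold higher, 4.72 to 5.69), where the median over transcripts with a mean of at least 5 RPM was 4.01-fold higher. As a Middle-class transcript piwi had less than 100 RPM in the untreated Piwi library. Its reads were thus already more abundant in control KD than in untreated cells, and the cause was not tested. The fs(1)Yb mRNA gave 29.5 RPM in control KD and 44.5 RPM in this library (1.51-fold higher, 0.881 to 2.63, but 1.43 below the table median). Small RNA reads of this gene therefore do not check the label. The genotype label of this library names the control RNAi, while its title and the header of its deposited column name Yb. The High class held 44.9% of the reads in control KD and 23.2% in this library, but which label is right was not tested.

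Invadolysin (202 to 19.9 RPM), CG13865, CG3164, CG11360, CG41099, Pis, Patr-1 and CG9257 had the smallest ratios, from 10.1-fold lower for Invadolysin to 5.56-fold lower for CG9257. After CHKov1 and ex, the largest ratios were those of the transcription factor bab1 (3.69 to 213 RPM), the receptor Ir68a (9.84 to 247 RPM), CG4928 (8.61 to 198 RPM), RpL13A (12.3 to 243 RPM), beta-Spec (27.1 to 446 RPM) and the ecdysone-induced factor Eip93F (20.9 to 320 RPM). The control KD value of bab1 is 3 reads. The table held 18.6% of all reads in control KD and 54.7% in the library labelled Yb KD, and the median log2 ratio over the 4924 transcripts with a mean of at least 5 RPM was 2.00. The High class had a median of 0.19, above 0 as given but 1.82 below this median, with 212 of 238 transcripts below it and no matched random list as low. Middle, Low and Zero transcripts had medians of 1.505, 1.91 and 1.12 over every transcript with a value, each above 0 as given and below the median by 0.50, 0.096 and 0.89. With their own filter of 5 RPM, the one behind the table median, the Low and Zero classes lay above it, by 0.15 and 0.21, and the Middle class below it by 0.49. Piwi-rich genes lay at −0.87 (47 of 48 below the median) and Armi-rich genes at −0.43 (40 of 46 below). Relative to the same median, cytoskeleton genes such as Act5C (263 to 1877 RPM) were at 0.82, ribosomal protein genes at 0.29, hemocyte markers such as ush (22.2 to 236 RPM) at 0.81, translation factors at 0.42, follicle genes at 0.37, heat shock genes at 0.45, nonsense-mediated decay genes at 0.35 and piRNA pathway genes at 0.13. Their percentiles among matched random lists were 99.96, 99.15, 98.88, 96.64, 93.28, 89.29, 82.14 and 71.34. Germline markers such as spn-E (79.99 to 199.2 RPM) had a median of 1.06, above 0 as given but 0.95 below the median of the table, at the 2.85 percentile. With a filter of 5 RPM they lay only 0.16 below it, at the 33.63 percentile, so their low position depended on the filter.

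Some transcripts stood out in the same direction in Armi iCLIP and in Piwi small RNA of the library labelled Yb KD. CG11360, Invadolysin, CG13865 and Pis were among the 8 smallest ratios in both assays, and ex was among the 8 largest in both. The High-class mRNA of Imp, an RNA-binding protein, had more signal as given in both. It went from 1217 to 3366 RPM in Armi iCLIP, 0.11 below the table median there. In Piwi small RNA it went from 1098 to 5864 RPM, 0.41 above the table median. Of the 238 High-class transcripts, 92 were higher as given in Armi iCLIP and 126 in Piwi small RNA. Across 3856 transcripts, which are not independent replicates, rho between the log2 ratios was 0.66. It was 0.87 in the High class, 0.84 in the Middle class, 0.52 in the Low class and 0.26 in the Zero class, and 0.74 for the Piwi-rich genes against 0.65 for all others. These assays share no control library.

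**Figure D3:**
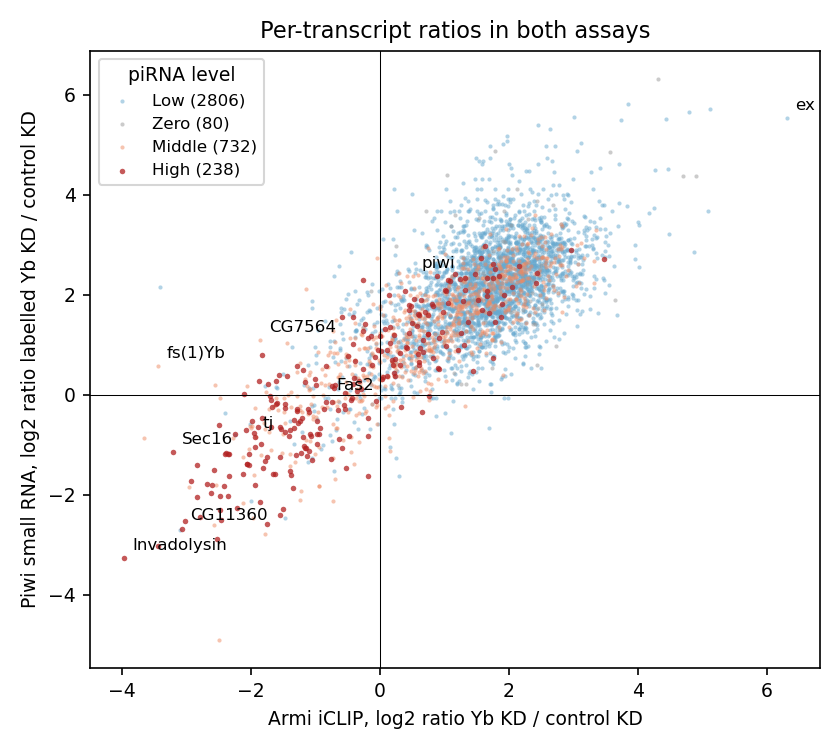
Each point is a transcript with a mean of at least 5 RPM in both assays; axes give log2 ratios of RPM + 1 in Armi iCLIP (x) and Piwi small RNA (y), coloured by piRNA level. High-class transcripts such as Invadolysin, CG11360 and tj lie at the lower left and ex at the upper right; rho was 0.66 over 3856 transcripts.

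The Zuc KD asks which Armi-bound RNAs carry a 5′ end open to ligation when the endonuclease is missing. Transcripts that rose most were those of ex, from 1.46 ± 1.01 to 69.7 ± 3.02 RPM (SD, n = 2), of Cda5, a chitin deacetylase, from 1.32 ± 0.238 to 62.3 ± 4.23 RPM, and of the receptor gene Ir68a, from 1.41 ± 0.370 to 40.8 ± 0.747 RPM. The adhesion molecule Fas2, the adaptor p130CAS, bbg, CG10019 and CG4168 rose too. Some transcripts of the High class fell, among them CG17514, from 564 ± 120 to 140 ± 0.146 RPM, CG32000, from 791 ± 377 to 232 ± 4.40 RPM, and brat, from 1825 ± 932 to 616 ± 8.82 RPM. The zuc mRNA was too low to check the knockdown, at 2.44 ± 1.82 RPM in control KD and 1.22 ± 1.24 RPM in Zuc KD.

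By limma's moderated test with Benjamini-Hochberg adjustment, the log2 change of ex was 4.91 (SE 0.334, adjusted p 1.377e-44), that of CG17514 −1.99 (SE 0.420, adjusted p 1.780e-04) and that of brat −1.46 (SE 0.502, adjusted p 0.0327), each higher or lower in both Zuc KD libraries than in both control libraries. CG6044, CG9416, CG32000, FBtr0340653, Tif-IA, a factor for rRNA synthesis, Sug and the RNA-binding protein gene unk completed the 8 named falls, with changes from −1.84 for CG6044 to −1.51 for unk. The tj mRNA did not pass (3039 ± 1561 to 1741 ± 130 RPM, log2 change −0.70, adjusted p 0.398). It did with centring (−1.04, adjusted p 0.0208), edgeR (adjusted p 5.469e-03) and DESeq2 (adjusted p 2.057e-04). Its change was −1.25 without control KD replicate 1 and −0.15 without control KD replicate 2, and with centring as well −1.37 and −0.71. The changes of dm (−0.98, adjusted p 0.1505), armi (0.34, adjusted p 0.583), piwi (−0.20, adjusted p 0.739) and fs(1)Yb (−0.60, adjusted p 0.255) did not pass with limma on the RPM as deposited. With centring, edgeR or DESeq2, 2 of armi, piwi, fs(1)Yb and tj passed in each, tj among them. The follicle gene zfh1 rose by 1.18 (adjusted p 0.0305), and of the hemocyte markers ush, Pxn and srp rose and crq fell.

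Of 4006 transcripts tested, 582 changed, 471 higher and 111 lower. The median change was 0.33. With each library centred on its median 379 changed to higher and 570 to lower; edgeR gave 452 higher and 549 lower and DESeq2 233 higher and 436 lower. These p-values rest only on the spread between these samples, pooled over transcripts of like RPM. The labels do not say that replicates were separate cultures. The SE was 0.329 for CG6044 (22.9 and 61.2 RPM in control KD) and 0.333 for CG4168 (13.7 and 12.7 RPM). A small p therefore does not show that a transcript's own replicates were close. The count depended on single libraries: it was 14 without Zuc KD replicate 1, 19 without Zuc KD replicate 2, 1406 without control KD replicate 1 and 2002 without control KD replicate 2. Groups did not overlap for 2423 transcripts (60.5%, where chance gives 33.3% if no library shifts as a whole). Most transcripts shifted together here, so the excess does not by itself show changes of single transcripts. Of the High class 40 fell and 2 rose among 238, of the Middle class 39 fell and 57 rose among 737, of the Low class 19 fell and 343 rose among 2487, and of the Zero class 9 rose and none fell among 30 (limma). With centring 138 fell and 6 rose in the High class, 191 fell and 68 rose in the Middle class, whose balance turns, 169 fell and 254 rose in the Low class, and 6 rose and none fell in the Zero class. The size of the fall of the High class depended on the control libraries: without control KD replicate 2 its median was −0.039, with 79 lower and 69 higher, and without control KD replicate 1 it was −0.84, with 176 lower and 14 higher. With centring as well, a setting chosen after seeing the data, these were −0.60 (157 lower, 24 higher) and −0.96 (189 lower, 12 higher).

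Gene lists were tested with camera at a preset inter-gene correlation of 0.01. The High class (median −0.47, adjusted p 3.097e-21; median −0.039 without control KD replicate 2 and −0.84 without control KD replicate 1), Piwi-rich genes (−0.80, 7.923e-18) and Armi-rich genes (−0.75, 1.179e-14) were lower than other transcripts. The Middle class (0.077) was lower than others too (5.740e-04), although its median and mean were above 0 as given, and −0.26 with centring. The Low class (0.41, adjusted p 4.467e-06), Zero class (0.67, 2.728e-03), heat shock and chaperone genes (0.91, 1.458e-03) and nonsense-mediated decay and helicase genes (0.80, 0.0303) were higher. With the correlation estimated from the data none of these held (adjusted p 0.731 for each). Cytoskeleton genes (0.84, adjusted p 0.0852), follicle genes (0.68, 0.0924), hemocyte markers (1.17, 0.256), translation factors (0.50, 0.256), germline markers (0.038, 0.276), ribosomal protein genes (0.22, 0.319) and piRNA pathway genes (0.21, 0.788) did not pass, and the last-named 3 medians turn to −0.30, −0.12 and −0.12 with centring. Members that passed over all transcripts and, after the slash, adjusted over the list alone were 40/51 lower for High, 12/20 lower for Piwi-rich, 12/14 lower for Armi-rich, 5/10 higher for heat shock, 3/9 higher for cytoskeleton, 3/5 higher for nonsense-mediated decay and 5/6 higher for follicle genes. With centring they were 138/153 lower for High, 39/44 lower for Piwi-rich and 37/42 lower for Armi-rich, and 5/8, 4/8, 3/3 and 4/4 higher for heat shock, cytoskeleton, nonsense-mediated decay and follicle genes. For the remaining lists these were 343/343 higher and 19/19 lower for Low, 57/53 higher and 39/38 lower for Middle, 9/13 higher for Zero, 3/3 higher and 1/1 lower for hemocyte markers, 2/2 higher for translation factors, 1/1 higher and 1/2 lower for germline markers and 1/1 higher for piRNA pathway genes, and no ribosomal protein gene passed either way. With centring 1/1 higher and 4/4 lower germline markers, 0/2 higher and 1/2 lower piRNA pathway genes, 2/3 higher and 1/1 lower hemocyte markers, 1/1 higher translation factors and 1/0 lower ribosomal protein genes passed.

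**Figure D4:**
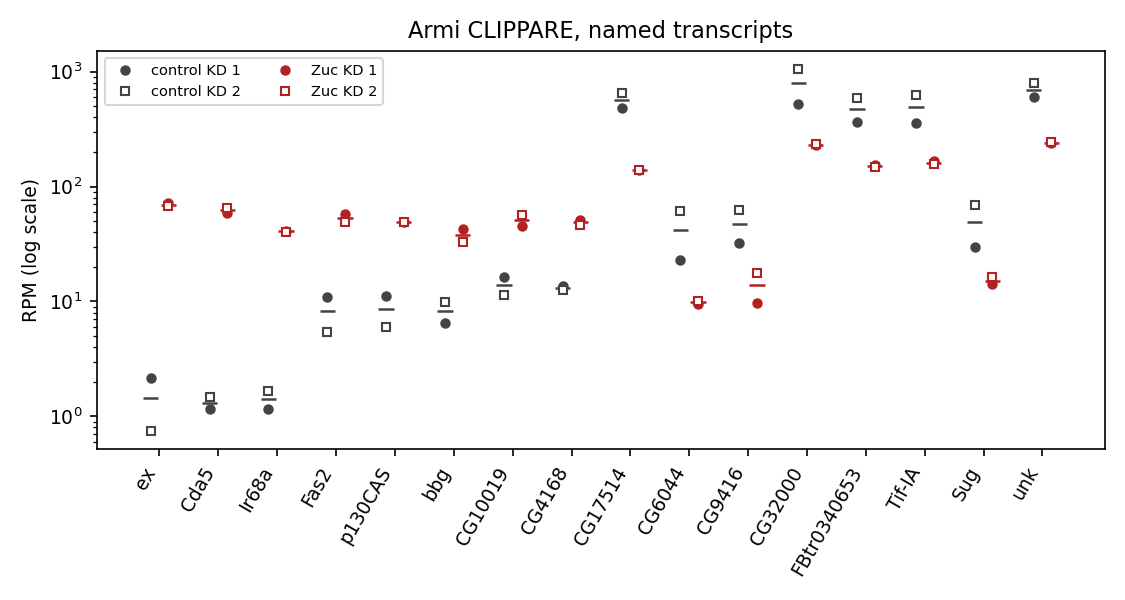
RPM on a log scale in each CLIPPARE library for the 16 transcripts named by the rule, with circles and squares for replicates 1 and 2, bars for group means, grey for control KD and red for Zuc KD. The 8 on the left rose, from ex at 1.46 to 69.7 RPM, and the 8 on the right fell, with CG17514 at 564 to 140 RPM.

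Both substitution mutants of Myc-Armi were set against WT Myc-Armi to ask what the altered protein binds. The mRNAs of the small heat shock proteins Hsp23 and Hsp26 stood out: Hsp23 had 48.7 RPM with WT, 2182 RPM with D862A (44.8-fold higher, 37.5 to 53.9) and 1585 RPM with R949A (32.5-fold higher, 27.2 to 39.2). Ribosomal protein mRNAs such as RpL38 (33.0 RPM with WT, 821 RPM with D862A and 629 RPM with R949A) were higher with both mutants, in 82 of 82 cases each. The piRNA source tj had 3082 RPM with WT, 2618 RPM with D862A and 2691 RPM with R949A, which is 1.96 and 1.87 log2 units below the table medians. The armi transcript, which here includes the transfected construct, had 5235, 5157 and 3950 RPM, and the labels do not say whether endogenous Armi was depleted.

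For D862A, CG10103 (5.11 to 202 RPM), the ecdysone-degrading enzyme gene Cyp18a1 (7.07 to 247 RPM), Ef1beta, RpL38, CG5010 and RpL21 followed Hsp23 and Hsp26, and for R949A Ef1beta (10.2 to 290.0 RPM), CG32230, ImpL3, RpL38, RhoL and viaf. The smallest ratios for D862A were those of CG32791 (314 to 56.7 RPM, 5.53-fold lower), Invadolysin, CG7564, CG32000, Patr-1, sl, CG11360 and CG9940. For R949A they were those of CG32791 (5.11-fold lower), CG32000, CG41099, CG7564, sl, Nipped-A, Invadolysin and CG11360. The fs(1)Yb mRNA was 3.61-fold lower with D862A (2.97 to 4.41) and 2.49-fold lower with R949A (2.08 to 2.99). The zuc mRNA went from 1.18 RPM, or 3 reads, to 24.7 and 22.3 RPM. The piwi mRNA was 1.81-fold and 2.15-fold higher as given but 0.87 and 0.57 below the table medians.

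The table held 33.2% of all reads with WT, 63.3% with D862A and 63.8% with R949A, and the median log2 ratios were 1.73 over 4585 and 1.68 over 4473 transcripts. The High class had medians of −0.11 and −0.018, with 232 and 231 of 238 transcripts below the table median and no matched random list as low. The Middle class lay at 0.77 and 0.80, above 0 as given and below the table medians by 0.96 and 0.88, the Low class at 2.00 and 1.97 and the Zero class at 3.05 and 3.04. Relative to the table medians, heat shock genes were at 1.91 and 2.07, ribosomal protein genes at 1.59 and 1.27, piRNA pathway genes at 0.96 and 0.63, cytoskeleton genes at 0.28 and 0.45 and translation factors at 0.14 and 0.060, with percentiles of 100, 100, 98.42, 98.75 and 92.25 for D862A and 100, 100, 93.72, 99.33 and 88.05 for R949A. Germline markers had medians of 0.21 and 0.79, but lay 1.51 and 0.89 below the table medians, at the 0.42 and 6 percentiles. Follicle genes, nonsense-mediated decay genes and the 3 hemocyte markers measured were above 0 as given and below the table medians, by 0.43, 0.43 and 0.93 for D862A and by 0.18, 0.33 and 0.57 for R949A. Their percentiles were 62.58, 45.48 and 18.21 for D862A and 79, 53.2 and 27.62 for R949A, so they were not low for their RPM.

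The mutants were compared with each other to ask whether they bind different RNAs, and they were nearly alike. Ribosomal protein mRNAs were somewhat more abundant with D862A, led by RpS15 (174 against 75.6 RPM, 2.30-fold higher, 2.05 to 2.57), then RpS14a and RpL14. Most mRNAs of the germline marker list were somewhat less abundant with D862A (11 of 13), among them Sxl (1135 against 1477 RPM), which is not confined to the germline. The tj mRNA had 2618 RPM with D862A and 2691 RPM with R949A.

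After RpL14, Arc1, RpS25, RpS3 and RpL7 were among the largest ratios, and mol (82.1 against 128 RPM), dos, vlc, CG32758, CG12065, CG1146, fl(2)d and bond were the smallest. The median log2 ratio was 0.024 over 4963 transcripts with a mean of at least 5 RPM, and 94.4% of these lay within 1 log2 unit. Of the 276 beyond it, 185 were higher with D862A and 91 with R949A. With a mean of at least 20 RPM, 99.3% of 3225 transcripts lay within 1 log2 unit. The median was 0.30 for ribosomal protein genes (71 of 82 higher with D862A, 100 percentile), 0.17 for heat shock genes (99.92 percentile), −0.31 for germline markers (11 of 13 lower, 0.09 percentile) and −0.040 for the High class. Across 4304 transcripts, which are not independent replicates, the ratios to WT correlated at r = 0.966 with a covariance of 2.21. Simulated mutants that do not differ from a shared WT column gave r = 0.674 and a covariance of 0.0456. Their noise was that between the untreated Armi iCLIP replicates (coefficient of variation 5.85%), since Myc-Armi has 1 column per condition. No shift of the WT column was simulated, so the contrast does not exclude an error in that column. With 1 WT column the control could not be split. Of 995 transcripts with a mean of at least 100 RPM in both ratios, 35 had opposite signs, and those with the largest smaller ratio were Eb1 (−0.19 and 0.18), Map205 (−0.13 and 0.23), sqd (−0.13 and 0.11), msk (−0.099 and 0.23) and CG10979 (0.097 and −0.13), each below the table median in both.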

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

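None of the results in this part had a test chosen after it was seen; the difference between the assays was not tested, since each has 1 value per condition. Some transcripts had less Armi signal in the Yb KD column but more Piwi-bound small RNA in the library labelled Yb KD. Of 531 transcripts with a mean of at least 100 RPM in both, 50 had opposite signs, 48 of them lower in Armi iCLIP and higher in Piwi small RNA. The 5 named by the rule were CG7564, Nopp140, a nucleolar chaperone gene, the kinase gene Abl, l(1)G0289 and the HMG-box gene Dsp1. CG7564 had 322 RPM in control KD and 88.4 RPM in Yb KD Armi iCLIP against 71.4 and 154 RPM in Piwi small RNA, a difference of log2 ratios of −2.948. For Nopp140 the difference was −2.0, for Abl −1.271, for l(1)G0289 −2.136 and for Dsp1 −1.408. All 5 lay below the table median in both assays, and only 2 of the 50 stayed opposite when both ratios were set against their table medians, so the opposite signs of these 5 follow from where 0 is placed. With that placing 81 of the 531 were opposite, 58 of them below the median in Armi iCLIP and above it in Piwi small RNA. In each of these values the genotype label of the Piwi library remains in conflict with its title.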

How the results depend on the processing

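The centred fits that also leave out a control library, and the filter at 5 RPM for the Piwi libraries, were chosen after seeing the data; the other settings were planned. The tests planned for the Yb KD and Myc-Armi columns, with their alternatives, were not run, because each condition has 1 column. No paired analysis was possible because there are no replicate columns to pair, and so no replicate was left out of the relation between the Yb KD assays. Unless a reason is given, the cause of a shift was not tested.

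For Zuc KD the 582 changed transcripts became 45 with no filter (9856 tested) and 211 with a filter of 20 RPM (1750 tested), where different numbers of transcripts are adjusted together. There were about 9.5e2 with centring, 379 higher and 570 lower, against 471 higher and 111 lower as reported, 1001 with edgeR, 452 higher and 549 lower, and 669 with DESeq2, 233 higher and 436 lower. Leaving out 1 library gave 14 to 2002. Centring and leaving out control KD replicate 1 or 2 gave 1507 or 1388. With the replicate block the count was 545, and same-numbered libraries of the groups correlated at 0.049, so the numbers show no pairing. The High class, with 40 lower and 2 higher as reported, had 23 lower and 0 higher with the replicate block. With no filter it had 0 lower and 0 higher. High minus Low was −0.88 and ranged from −1.07 to −0.67 when a library was left out (−1.07 without control KD replicate 1, −0.67 without control KD replicate 2), and centring does not change this difference. The High median of −0.47 was −0.84 without control KD replicate 1 and −0.039 without control KD replicate 2, and with centring as well −0.96 and −0.60. Without replicates in a group, the lone library is assumed to vary like the other group.

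Of the list calls, High, Middle, Low, Zero, Piwi-rich, Armi-rich, heat shock and nonsense-mediated decay were lost with an estimated correlation (adjusted p 0.7307 each) and with fry (adjusted p 0.2819, but 0.5048 for High). Fry gave the Middle class, whose median is above 0, the other direction at 0.8273; it sets no list against other transcripts. With centring cytoskeleton genes passed (adjusted p 0.01409), and the calls of the other lists kept their side, but with an estimated correlation as well none held (adjusted p 0.3315 for cytoskeleton and 0.3219 or more for the others).

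Among columns without replicates, High minus Low kept its sign under every setting. In Yb KD Armi iCLIP it was −2.26, and −2.39 and −1.81 with pseudocounts of 0.1 and 5 RPM, −2.33 with a filter of 20 RPM and −1.93 with none. In Piwi small RNA it was −1.72, and −2.04, −1.14 and −2.11 with the same pseudocounts and filter, and −1.96 with a filter of 5 RPM. For D862A it was −2.10, and −2.24, −1.64, −2.02 and, with no filter, −1.83; for R949A −1.99, and −2.11, −1.55, −1.92 and −1.67; between the mutants −0.083, and −0.059 with a filter of 20 RPM. Centring moved the High median to −2.12 in Yb KD Armi iCLIP, −1.83 for D862A, −1.69 for R949A and −0.064 between the mutants, and reversed it to −1.82 in Piwi small RNA.

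Centring also reversed list medians by construction, since each lay between 0 and the table median. In Yb KD Armi iCLIP these were germline markers (−0.93), piRNA pathway genes (−0.047) and the Middle class (−0.59). In Piwi small RNA they were germline markers (−0.95) and the Middle (−0.50), Low (−0.096) and Zero (−0.89) classes over every transcript with a value; with the filter of 5 RPM that the table median has, Low (0.15) and Zero (0.21) do not reverse, and germline markers (−0.16) and Middle (−0.49) do. For D862A they were follicle genes (−0.43), germline markers (−1.51), hemocyte markers (−0.93), nonsense-mediated decay genes (−0.43) and the Middle class (−0.96), and for R949A follicle genes (−0.18), germline markers (−0.89), hemocyte markers (−0.57), nonsense-mediated decay genes (−0.33) and the Middle class (−0.88). Between the mutants they were nonsense-mediated decay genes (−0.0045) and translation factors (−0.011), both close to 0 either way, and in untreated cells the Middle class (0.39), Armi-rich genes (0.067) and nonsense-mediated decay genes (0.29). Single genes reversed likewise: armi (−0.057), piwi (−1.07) and zuc (−0.38) in Yb KD Armi iCLIP, armi (−0.12), fs(1)Yb (−1.43) and zuc (−1.79) in Piwi small RNA, armi (0.60) and zuc (0.15) in untreated cells, and piwi with D862A (−0.87) and R949A (−0.57).

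In untreated cells rho of 0.70 became 0.56 with a filter of 20 RPM and 0.81 with none, and 0.69 to 0.70 when an Armi replicate was left out; the High share of the Armi table was 41.7% to 41.8%. The rank correlation between the Yb KD assays, 0.66, became 0.64 and 0.74 with pseudocounts of 0.1 and 5 RPM and 0.78 with a filter of 20 RPM. Of 300 values of 20 named Zuc KD transcripts, 255 kept their side of the threshold. In 16 values armi, piwi, fs(1)Yb or tj gained a call. In fits on all libraries, centring, edgeR and DESeq2 each gave a call to 2 of these genes, tj (−1.04 with centring) and another. Others of the 16 came from fits with 1 control library, where the spread is that of the Zuc KD libraries alone. Without control KD replicate 1 the change of tj was −1.25, and −1.37 with centring as well. Without control KD replicate 2 it was −0.15, and −0.71 with centring as well. In 29 a call was lost, 8 with no filter, 11 without Zuc KD replicate 1 and 10 without Zuc KD replicate 2. Depth limits the Piwi knockdown libraries most, where 3 reads are 3.69 RPM in control KD.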

Other observations

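The relations of the Yb KD ratio to Zuc KD and to the mutants, and the use of the values in this part as tests of explanations, were chosen after the results were seen, although the differences of −2.257 and −0.671 themselves come from planned settings. Transcripts with larger changes in Zuc KD CLIPPARE also had larger ratios in the Yb KD column of Armi iCLIP. Across 3381 transcripts, which are not independent replicates, rho between the Yb KD ratio in Armi iCLIP and the Zuc KD change in CLIPPARE was 0.75, and 0.80 in the High class, 0.82 in the Middle class and 0.66 in the Low class. The Yb KD ratio followed those of the mutants less closely, with rho of 0.43 for D862A and 0.42 for R949A.

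High-class transcripts such as tj, Invadolysin, CG11360 and Sec16 had less Armi signal in the Yb KD column relative to Low-class transcripts, by −2.257 (counting interval −2.30 to −2.20). One factor for each library would leave this difference at 0 and is excluded. The classes were drawn from 1 untreated Piwi library that is no part of this ratio. Control KD set against untreated Armi iCLIP, which does not hold that library either, gave a difference of 0.3179, of the other sign. This check therefore cannot decide on the choice of classes. It shows that the difference can move without Yb depletion by more than the counting interval covers. More unspecific mRNA fragments in the Yb KD library remain open: within the High class the 90th percentile of the ratio was 13.85 times the 10th, and whether this spread follows mRNA level cannot be told here, since RNA levels were not measured. That Armi without Yb is no longer led to piRNA sources may explain the pattern as well, and these values do not separate the 2 readings.

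The control KD libraries of CLIPPARE differed more than the Zuc KD libraries, with a chi-square per degree of freedom of 12.5 against 2.52. High-class transcripts such as tj (1935 and 4143 RPM) and brat (1166 and 2484 RPM) differed most. A single factor between the libraries is excluded by their High minus Low difference of 0.3946 (counting interval 0.360 to 0.416). A wrong label, with control KD replicate 1 being a Zuc KD library, is argued against by the difference of both Zuc KD libraries from that replicate alone, −0.671, where the Zuc KD libraries differ by 0.016 from each other. A partial mix of material was not tested, and no biological explanation was tested, since the labels give the replicates the same treatment.

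Among transcripts with a symbol, 19 rose at least 4-fold in Zuc KD CLIPPARE, among them ex, Cda5, Ir68a, CG1317, CHKov1, neo, bab1, CG30076, Eip93F, Gli and the homeotic gene Antp. Their median log2 ratio in Yb KD Armi iCLIP was 3.437, where 95% of matched random lists lay between 1.05 and 2.05, so noise of low CLIPPARE counts is argued against; Fas2 went the other way (−0.80). That median lay 1.721 above that of the Low class, so the shift shared by Low transcripts is not enough. In the library labelled Yb KD their Piwi small RNA median was 3.683 (matched lists 1.53 to 2.51), while with D862A and R949A they lay at the 52.25 and 59.64 percentiles. Higher RNA levels of these genes in cells that lack a piRNA factor may be the source, as a hypothesis that stays open because RNA levels were not measured here.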
